A study of Rattus norvegicus with 20 samples.

How the data were processed

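RNA of 20 samples of primary rat islets was measured on an Affymetrix rat expression array, with 1 array per sample. Per the labels, islets were cultured in medium with 10% serum and 8 mM glucose, received virus for 18 h where they received any, and were collected 48 h after virus was added. Total RNA was labelled with biotin. The titles, the sample characteristics and the series design name untreated islets and viruses for GFP, Nr4a1 and Nr4a3, while the treatment protocol in the labels names viruses for beta-galactosidase and Nkx6-1. Groups follow the titles and characteristics, and nothing measured here settles the conflict. The labels call the replicates biological, but the animals behind each sample are not given in the sources used here, so every p measures the spread between these samples.

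The deposited values are probe set intensity values made by the authors with robust multi-array average (RMA), which corrects background, normalizes by quantiles and summarizes probes, in a version not given in the sources used here. They are on a linear scale, whereas a log scale had been assumed before the data were examined, and they were log2-transformed with no further scaling. Detection p-values, scan dates and array batches were not used here. The number of arrays limits the precision.

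The table holds 31099 probe sets. Gene symbols came from the probe table of the array: 9831 probe sets have no symbol, 436 have several and 20832 have 1. Of these, 20764 were checked through the gene identifier against current symbols, and 0 changed. For each of 14217 genes the probe set with the highest mean over all arrays was used, chosen without regard to group, and 4525 genes had more than 1 to choose from. Another 57 control probe sets served only to judge arrays. Genomic positions were not used here.

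A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests, 16 residual and 3.64 prior degrees of freedom. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The 4 comparisons were Nr4a1 against GFP, Nr4a3 against GFP, Nr4a1 against Nr4a3 and GFP against untreated, and log2 changes are the first group minus the second. The overlap of both responses was set against lists drawn independently, against 50 simulated sets of unchanged groups with shared controls, and against 20 splits of the GFP arrays into sets of 2 and 3.

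Gene lists (28, with 737 distinct genes, 662 of 761 entries measured) were written from general knowledge before the data were examined. They are the NR4A family, for which only values are given, the genes of the study, G1/S and E2F target genes, G2/M and mitosis genes, the anaphase-promoting complex, CDK inhibitors and the RB family, p53 target genes, genes of beta cells, other islet hormone cells, acinar cells, duct cells, endothelial cells, fibroblasts and stellate cells, macrophages and leukocytes, and beta cell disallowed genes. The others are interferon response, NF-kB and inflammatory, unfolded protein response, immediate early, cholesterol synthesis, lipogenesis and fatty acid oxidation, glycolysis, oxidative phosphorylation, apoptosis, exocytosis and calcium channel, neuronal and calcium signalling, heat shock and ribosomal protein genes. The 27 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance or, in its mixed form, in either direction. Each was adjusted over the lists of a comparison. Of the 10 genes of the study, which were chosen from knowledge of this study, 9 are also on another list, as are 2 of 49 G2/M, 3 of 49 G1/S, 3 of 24 beta cell and none of the 24 acinar or 16 endothelial genes. Fits with the mean of acinar genes as a covariate were ordinary linear fits without moderation. Means of lists per array were compared by exact permutation of 5 against 5 arrays, two-sided.

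Genes to name were chosen by a rule written before the data were examined. They were Nr4a1, Nr4a2, Nr4a3 and the genes of the study; the 8 largest rises and 8 largest falls with an adjusted p under 0.05 and all arrays of one group beyond all of the other, without unnamed loci and olfactory or vomeronasal receptors; and of each described list up to 4 genes with the smallest adjusted p. Examples from the lists took the genes chosen to 55, 48, 30 and 19 in the comparisons in the order above, more than the 30 aimed for in both comparisons with GFP as control. Of the genes chosen for Nr4a3 against GFP, 1 is not given here.

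Alternatives fixed before the data were examined were fits to only the 10 arrays compared, the replicate number as a block, a trended and robust variance, array weights, a repeated quantile normalization, median centring, filters on dim genes, all probe sets, the mean of a gene's probe sets, a 2-fold or stricter threshold, untreated as control and each array left out in turn. Leaving Nr4a3 replicate 2 out of every comparison was added after seeing the data. The model was tested on simulated data of 14217 genes, with known changes in a small part of them. Their spread was independent between genes and equal across arrays, unlike the data, so the rates below may not hold for the data. Of changes of 1 on the log2 scale it recovered 94.0%, 90.6%, 95.1% and 93.7% in the 4 comparisons, of changes of 0.5 it recovered 56.7%, 66.7%, 46.4% and 63.9%, and false calls were 5.06%, 4.49%, 5.23% and 3.87% of the calls.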

Results

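Expression was measured on 20 arrays of islets isolated from male Wistar rats aged 8 weeks, with 1 array per sample. Islets stayed untreated or received an adenovirus carrying green fluorescent protein (GFP), Nr4a1 or Nr4a3, and each of the 4 groups had 5 arrays. Nr4a1 and Nr4a3 are orphan nuclear receptors that act as transcription factors, and Nkx6-1 is a homeodomain transcription factor of the beta cell. The stated interest of the series is whether both receptors raise cell cycle genes that belong to the route by which Nkx6-1 drives beta cell division. Array medians lay between 98.9 and 103 on the linear intensity scale and single values between 7.69 and 34261. Precision is limited by the number of arrays. Nr4a3 replicate 2 stood apart from the other 19 arrays. Its mean correlation with the others across genes was 0.941, against 0.982 to 0.989 for the rest, and genes are not independent replicates. Its beta-actin control probe sets for the 3' and the 5' end of the transcript differed by 4.62 on the log2 scale, against 1.5 to 2.21 in the other 19 arrays. The array was kept, and counts are given with and without it.

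The probe sets for the delivered genes did not follow the labels. The Nr4a1 probe set averaged 5.99 ± 0.12 (SD, log2 intensity, n = 5) in the arrays labelled Nr4a1 and 6.07 ± 0.09 (SD, n = 5) in the GFP arrays, a log2 difference of -0.07 ± 0.09 (SE), and it differed from GFP by 0.02 ± 0.09 in the arrays labelled Nr4a3. The brightest Nr4a3 probe set averaged 5.82 ± 0.19 (SD, n = 5) in the arrays labelled Nr4a3 and 5.63 ± 0.17 (SD, n = 5) in the GFP arrays, a log2 difference of 0.19 ± 0.10 (SE, limma adjusted p = 0.421). Nr4a3 did rise in the arrays labelled Nr4a1, by a log2 of 0.44 ± 0.10 (SE, limma adjusted p = 0.00562). A dimmer Nr4a3 probe set was higher than GFP by 0.75 ± 0.23 in the arrays labelled Nr4a1 (limma adjusted p = 0.0636 over all probe sets, and 0.000305 without Nr4a3 replicate 2) and by 0.50 ± 0.23 in those labelled Nr4a3 (adjusted p = 0.422 with limma, and a difference of 0.19 with 0.569 without Nr4a3 replicate 2). Without Nr4a3 replicate 2 it was higher in the Nr4a1 than in the Nr4a3 arrays by 0.55 ± 0.13 (limma adjusted p = 0.0548). The remaining Nr4a3 probe set differed from GFP by -0.09 in the Nr4a1 group and, in the Nr4a3 group, by 0.16 with all arrays and -0.06 without Nr4a3 replicate 2. Nr4a2 differed from GFP by a log2 of -0.04 in the Nr4a1 group and 0.35 in the Nr4a3 group, and neither passed the test. Where these probe sets lie relative to the part of each transcript carried by the virus is not given in the sources used here, so they check neither the labels nor the delivery. They leave an exchange of the labels Nr4a1 and Nr4a3 open. It would turn the sign of each difference between these groups and exchange all their results against GFP.

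The comparison of Nr4a1 with GFP asks what added Nr4a1 changes beyond the virus itself. Cell cycle genes were higher in the arrays labelled Nr4a1: Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose 2.64-fold (log2 1.40 ± 0.24, SE, n = 5 per group), and Ccne1, which encodes the S phase cyclin E1, rose 1.78-fold (log2 0.83 ± 0.14). Genes of acinar cells, which make digestive enzymes, rose more, 21 of 24 with a list median of 5.54-fold, while 7 of 24 beta cell genes and 7 of 16 endothelial cell genes fell. The largest rises were Fga, a fibrinogen chain, at 34.8-fold (log2 5.12 ± 0.63), Ddit4l, an inhibitor of mTOR signalling, at 17.0-fold (log2 4.09 ± 0.42), and the secretin gene Sct at 15.7-fold (log2 3.97 ± 0.31). Of 14217 genes, 876 rose and 363 fell at a limma adjusted p under 0.05, and 148 rose and 3 fell by at least 2-fold. The 3' minus 5' difference of the GAPDH control probe sets was 0.271 to 0.357 in the Nr4a1 arrays and 0.499 to 0.739 in the GFP arrays. Ranges for beta-actin overlapped, and whether RNA quality adds to these counts was not tested. Without Nr4a3 replicate 2, which enters through the shared estimate of spread, 1739 rose and 975 fell, and all 1239 genes called before were among them. Without Nr4a1 replicate 1 the total was 742, of which 164 fell. A fit to only these 10 arrays called 2853 genes (1810 up, 1043 down) and a fit with array weights 3576 (1997 up, 1579 down). In 2302 genes (16.2%) all 5 arrays of one group lay beyond all 5 of the other, against 0.794% by chance.

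Further genes among the largest rises were Gucy2c, the intestinal receptor guanylate cyclase C (log2 3.97 ± 0.27), Nnat, which encodes neuronatin (3.81 ± 0.22), and Gas2, a growth arrest-specific gene (3.56 ± 0.19). The trypsin inhibitor gene Spink1 rose by 3.59 ± 0.69 and its relative Spink1l by 3.68 ± 0.55. All 8 genes lay higher in each of the 5 Nr4a1 arrays than in any GFP array, as the rule for naming them required. The largest falls were smaller. Rnf152, a lysosomal ubiquitin ligase gene, fell by 1.07 on the log2 scale, and the amino acid transporter gene Slc43a2 changed by -1.01 and Zfp451 by -0.98. Kdr and Nrp1, a receptor and a co-receptor of vascular endothelial growth factor, changed by -1.0 and -0.99, and Cd93, a surface protein gene of endothelial cells, by -0.97. The receptor genes Il6r and Igf1r each changed by -0.95. Adjusted p of these 8 ranged from 0.000449 for Il6r to 0.0372 for Zfp451. Zfp451 lost its call without any 1 of the 5 GFP arrays or without Nr4a1 replicate 2, 3, 4 or 5 (limma adjusted p from 0.0531 to 0.120), and Kdr without GFP replicate 1 or 4 or Nr4a1 replicate 1 or 2 (0.0511 to 0.0657). Under other alternatives the limma adjusted p reached 0.613 for Zfp451, 0.160 for Rnf152 and 0.0827 for Slc43a2. Over all alternatives their changes shrank to as little as -0.29, -0.54 and -0.68.

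The G2/M and mitosis genes rose together in the arrays labelled Nr4a1. Of 49 measured, 36 rose and none fell over all genes, and 43 rose and 1 fell when adjusted over the list alone. Their median log2 change was 0.76 (camera adjusted p = 7.42e-27, and adjusted p = 0.198 with an estimated correlation). Nuf2 of the kinetochore rose by 1.15 ± 0.17, the mitotic cyclin gene Ccnb1 by 1.17 ± 0.18, Birc5, which encodes survivin, by 0.85 ± 0.14, and the proliferation marker Mki67 by 1.11 ± 0.26 (log2 ± SE, n = 5 per group). The mean of this list was higher in all 5 Nr4a1 arrays than in any GFP array, by 0.74 (exact permutation p = 0.00794, two-sided, the smallest that 5 against 5 arrays can give, and 0.0278 after adjustment over the lists). Among the G1/S and E2F target genes, 19 of 49 rose and none fell, and 28 rose and 1 fell when adjusted over the list alone. The median was 0.40 (camera adjusted p = 1.55e-13, and adjusted p = 0.191 with an estimated correlation). Examples are Ccne1, the histone chaperone subunit gene Chaf1a (0.57 ± 0.10) and Mcm3, which encodes a subunit of the replicative helicase (0.76 ± 0.14). Of 19 genes of the anaphase-promoting complex, 5 rose, and 6 when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 6.8e-05, and adjusted p = 0.198 with an estimated correlation). Besides Ube2c they include Anapc16 (0.49 ± 0.09). Acinar cell genes moved with these lists, with a mean of 10.60 ± 0.59 (SD, log2, n = 5) in the Nr4a1 arrays and 8.21 ± 1.05 (SD, n = 5) in the GFP arrays.

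CDK inhibitors, which brake the cell cycle, went both ways. Of 12 such genes with the RB family, 3 rose and 2 fell, 5 and 2 when adjusted over the list alone, and the list did not pass limma's camera (median 0.04, adjusted p = 0.273). Its mean was higher by 0.19 in the Nr4a1 arrays, with 4 of 5 above all GFP arrays (exact permutation p = 0.0159, two-sided, adjusted 0.0404). Cdkn2d rose by 0.98 ± 0.11 and Cdkn3, whose product dephosphorylates cyclin-dependent kinases, by 1.08 ± 0.28 (log2 ± SE, n = 5 per group), while Cdkn1b, which encodes p27, fell by 0.34. Cdkn3 lost its call without Nr4a1 replicate 1 or 4 or GFP replicate 2 or 5 (limma adjusted p from 0.0522 to 0.0593). Cdkn1b lost its call without GFP replicate 1, 2, 3 or 5 or Nr4a1 replicate 1, 2, 4 or 5 (0.0525 to 0.0826).

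The 10 genes of the study were chosen from knowledge of this study and are not independent evidence. E2f1, Ccne1, Ube2c and Mki67 rose and Nkx6-1 fell, while Cdkn1a, Uhrf1, Cdk5r1, Vgf and Fos did not pass. When adjusted over the list alone, 5 rose and 1 fell. The E2F transcription factor gene E2f1 rose 1.49-fold (log2 0.57 ± 0.17, limma adjusted p = 0.0356, n = 5 per group) and Nkx6-1 changed by a log2 of -0.42 ± 0.12 (adjusted p = 0.0296). Uhrf1, which maintains DNA methylation at replication, differed by 0.49 ± 0.19 (limma adjusted p = 0.136) and Cdkn1a, which encodes p21, by -0.19 ± 0.14 (adjusted p = 0.549). The log2 differences of Cdk5r1, Vgf and Fos were -0.01, -0.06 and 0.13. E2f1 lost its call without GFP replicate 1, 2 or 3 or Nr4a1 replicate 1, 3, 4 or 5 (adjusted p from 0.0596 to 0.115), and Nkx6-1 without GFP replicate 1, 3 or 5 or Nr4a1 replicate 1 or 5 (0.0593 to 0.104). The list's median was 0.31 (camera adjusted p = 0.0471, and adjusted p = 0.409 with an estimated correlation). That call ended without GFP replicate 1 or 3, Nr4a1 replicate 5 or Nr4a3 replicate 2 (0.0582 to 0.130).

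**Figure D1:**
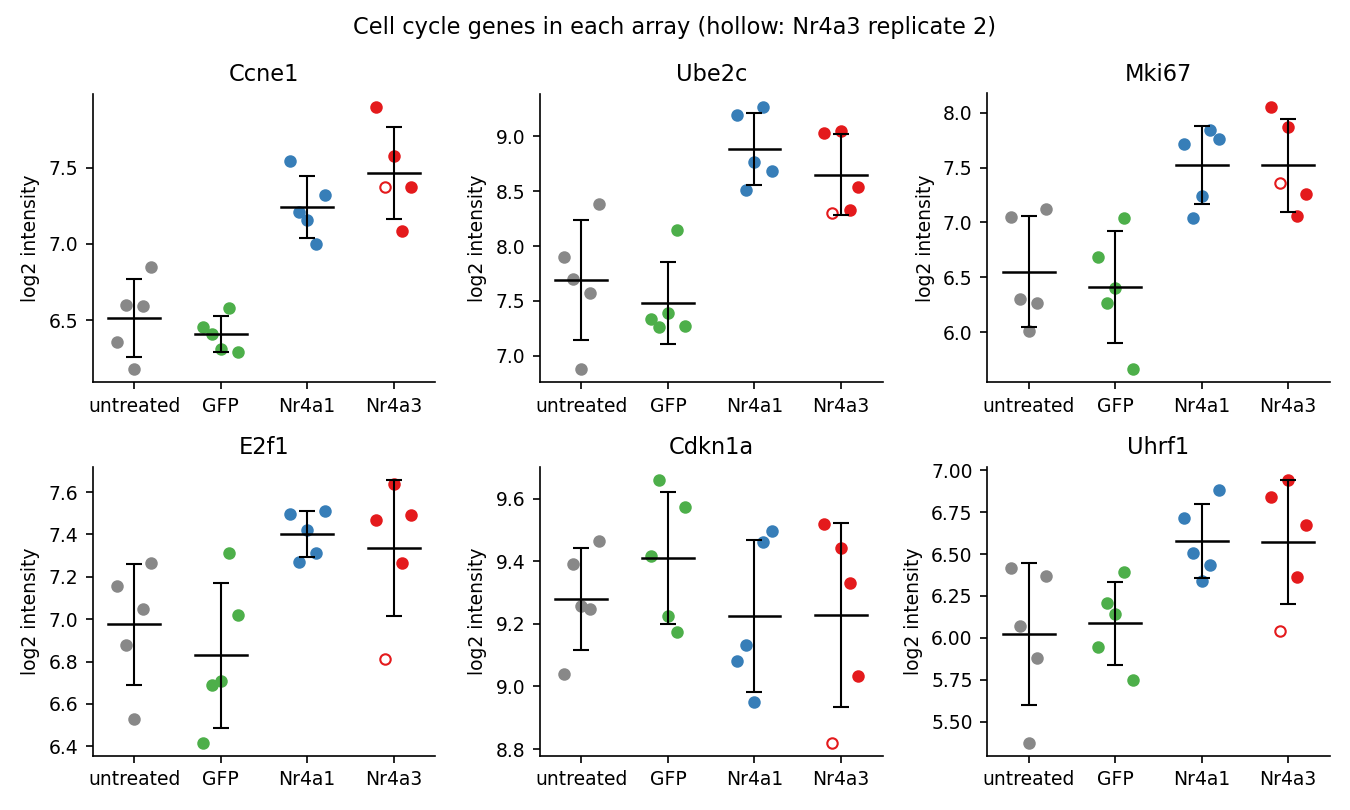
Each point is 1 array and gives the log2 intensity of Ccne1, Ube2c, Mki67, E2f1, Cdkn1a or Uhrf1, with lines at the group mean and bars of 1 SD (n = 5 per group) and Nr4a3 replicate 2 drawn hollow. Ccne1 averages 6.41 in the GFP arrays, 7.24 in the Nr4a1 arrays and 7.46 in the Nr4a3 arrays, while Cdkn1a averages 9.41, 9.22 and 9.23.

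Acinar cell genes rose in the arrays labelled Nr4a1: 21 of 24 rose and none fell, 22 rose when adjusted over the list alone, and the median log2 change was 2.47 (camera adjusted p = 2.94e-18, and adjusted p = 0.198 with an estimated correlation). Besides Spink1, the lipase gene Pnlip rose by 3.07 ± 0.44, the elastase gene Cela1 by 3.02 ± 0.50 and the carboxypeptidase gene Cpb1 by 3.30 ± 0.60 (log2 ± SE, n = 5 per group). The acinar mean differed by 2.39 between the Nr4a1 and GFP arrays, with all 5 Nr4a1 arrays above all GFP arrays (exact permutation p = 0.00794, two-sided, adjusted 0.0278). It also varied between control arrays, and untreated replicate 5 reached 10.47. Of 24 beta cell genes 1 rose and 7 fell, 1 and 9 when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 1.75e-06, and adjusted p = 0.270 with an estimated correlation). The incretin receptor gene Gipr fell by 0.76, and the potassium channel gene Kcnj11 changed by -0.57 and the transcription factor gene Pdx1 by -0.69. The arrays measured whole islets. Whether these falls arose within beta cells or went with the higher acinar values was not tested. Ins1 lay within 0.01 of the highest log2 value of its arrays, so a change in insulin transcripts would be compressed. Of 16 endothelial cell genes, 7 fell and none rose, 12 fell when adjusted over the list alone, and the median was -0.51 (camera adjusted p = 2.83e-09, and adjusted p = 0.198 with an estimated correlation). With Kdr they include Flt1 (-0.78), Emcn (-0.82) and Pecam1 (-0.58). None of the 23 fibroblast and stellate cell genes passed alone, with a median of -0.29 (camera adjusted p = 0.00483, and adjusted p = 0.609 with an estimated correlation). The duct cell genes (1 of 15 rose, median 0.05, limma camera adjusted p = 0.668), the other islet hormone cell genes (1 of 13 fell, median -0.08, camera adjusted p = 0.157), the macrophage and leukocyte genes (0 of 22, median -0.03, camera adjusted p = 0.454) and the beta cell disallowed genes (0 of 15, median -0.01, camera adjusted p = 0.730) did not pass as lists.

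**Figure D2:**
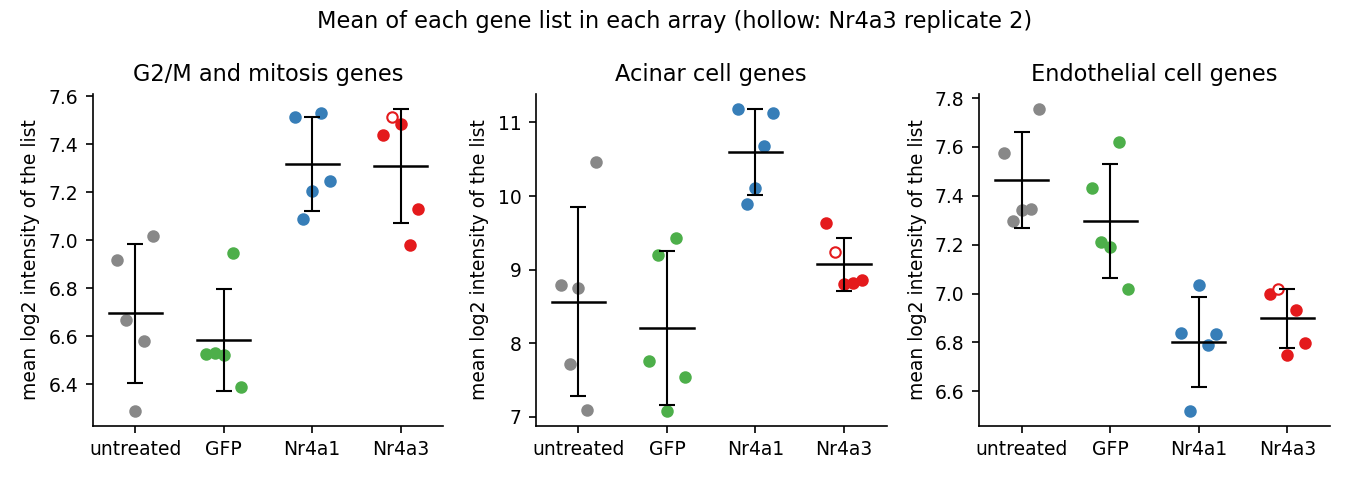
Each point is 1 array and gives the mean log2 intensity of the G2/M and mitosis, acinar cell or endothelial cell genes, with lines at the group mean, bars of 1 SD (n = 5 per group) and Nr4a3 replicate 2 drawn hollow. The acinar mean is 8.57 in the untreated, 8.21 in the GFP, 10.60 in the Nr4a1 and 9.07 in the Nr4a3 arrays, and the G2/M mean is 6.70, 6.58, 7.32 and 7.31.

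The comparison of Nr4a3 with GFP asks the same question for added Nr4a3. Cell cycle genes were higher here too: Ccne1 rose 2.07-fold (log2 1.05 ± 0.14, SE, n = 5 per group), Ube2c 2.25-fold (1.17 ± 0.24) and the marker of dividing cells Mki67 2.16-fold (1.11 ± 0.26). The largest rises were Sct at 13.9-fold (3.80 ± 0.31), Gucy2c at 12-fold (3.58 ± 0.27) and Nnat at 9.27-fold (3.21 ± 0.22). All 5 Nr4a3 arrays lay above all GFP arrays for each of them, as the rule for naming them required. Fewer genes were called than for Nr4a1: 249 rose and 25 fell at a limma adjusted p under 0.05, 58 and 1 by at least 2-fold. The 25 falls were 13 in the replicate block, 55 after a repeated quantile normalization, and with single arrays left out 5 (without GFP replicate 2) to 55 (without Nr4a3 replicate 2). A fit to only these 10 arrays called 122 genes (104 up, 18 down) and a fit with array weights 1027 (787 up, 240 down). Without Nr4a3 replicate 2, 472 rose and 55 fell, and 254 of the 274 genes called before were among them. The total of 274 became 158, 137, 160 or 130 without GFP replicate 1, 2, 3 or 5, and 127 or 144 without Nr4a3 replicate 1 or 3. Group ranges did not overlap in 658 genes (4.63%), against 0.794% by chance.

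Next after Sct, Gucy2c and Nnat came Ddit4l (log2 3.01 ± 0.42), Igfbp3, which encodes a carrier of insulin-like growth factors (2.97 ± 0.41), and Fga (2.80 ± 0.63). The enzyme genes Aadat of lysine breakdown and Gatm of creatine synthesis followed at 2.42 ± 0.30 and 2.35 ± 0.32. Among the largest falls, Kdr changed by -1.09 ± 0.26, the detoxifying enzyme gene Cyp1a1 by -0.81 ± 0.21, the growth factor receptor gene Flt1 by -0.72 ± 0.15 and the heme oxygenase gene Hmox1 by -0.66 ± 0.15. Prp2l1 changed by -0.65, Gipr by -0.64, the calcium channel gene Cacna1h by -0.63 and Il6r by -0.62, and adjusted p of these 8 ranged from 0.00563 for Gipr to 0.0482 for Cyp1a1. Leaving out single arrays ended the calls of 7 of these 16 genes, with these limma adjusted p. They were Fga (0.0519 to 0.0715, GFP replicate 1, 3 or 5 or Nr4a3 replicate 1 or 3), Kdr (0.0532 to 0.0966, GFP replicate 1, 2, 3 or 4 or Nr4a3 replicate 2, 3 or 5) and Cyp1a1 (0.0578 to 0.133, any GFP array or Nr4a3 replicate 1, 2, 3 or 5). The others were Hmox1 (0.0543 to 0.0780, GFP replicate 1, 2 or 5 or Nr4a3 replicate 1, 3 or 5), Prp2l1 (0.0625 to 0.0705, GFP replicate 1, 2, 4 or 5 or Nr4a3 replicate 1 or 5), Cacna1h (0.0578 to 0.147, GFP and Nr4a3 replicate 1, 2, 3 or 5) and Il6r (0.0604 to 0.110, GFP replicate 1, 2, 3 or 5 or Nr4a3 replicate 1, 3 or 5).

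G2/M and mitosis genes rose together in the arrays labelled Nr4a3 as well. Of 49 measured, 29 rose and none fell, and 44 rose when adjusted over the list alone, with a median log2 change of 0.74 (camera adjusted p = 3.16e-38, and adjusted p = 0.0769 with an estimated correlation). Nuf2 rose by 1.14 ± 0.17 and Spc25, another kinetochore gene, by 1.26 ± 0.22 (log2 ± SE, n = 5 per group). The list mean was higher in all 5 Nr4a3 arrays than in any GFP array, by 0.73 (exact permutation p = 0.00794, two-sided, and 0.0556 after adjustment over the lists). In the G1/S and E2F target list, 13 of 49 rose and none fell, and 29 rose when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 4.38e-19, and adjusted p = 0.0515 with an estimated correlation). The DNA polymerase gene Pole rose by 0.60 ± 0.10 and Chaf1a by 0.57 ± 0.10. Of 19 genes of the anaphase-promoting complex, 2 rose, Ube2c and Cdc16 (0.29 ± 0.07), and 4 when adjusted over the list alone. The median was 0.11 (camera adjusted p = 0.0122, and adjusted p = 0.449 with an estimated correlation), and the list's call ended without Nr4a3 replicate 1 (0.0902). Among CDK inhibitors and the RB family, Cdkn1c (0.63 ± 0.12) and Cdkn3 (1.23 ± 0.28) rose, 3 rose when adjusted over the list alone, and the median was 0.12 (camera adjusted p = 0.0470, and adjusted p = 0.146 with an estimated correlation). That list's call ended without any 1 of the 10 arrays except GFP replicate 4 (0.0520 to 0.132). Cdc16 lost its call without any GFP array or without Nr4a3 replicate 1, 3 or 5 (0.0584 to 0.10), and Cdkn3 without GFP replicate 1, 2, 3 or 5 or Nr4a3 replicate 1 or 3 (0.0622 to 0.0833). The acinar mean was 9.07 ± 0.36 (SD, log2, n = 5) in the Nr4a3 arrays, against 8.21 ± 1.05 (SD, n = 5) in the GFP arrays.

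Of the 10 genes of the study, Ccne1, Ube2c and Mki67 rose and none fell, and 5 rose when adjusted over the list alone, which is not independent evidence. E2f1 differed by 0.51 ± 0.17 (limma adjusted p = 0.152) and passed without Nr4a3 replicate 2 (0.64, adjusted p = 0.0252). Uhrf1 differed by 0.49 ± 0.19 (limma adjusted p = 0.263), Cdkn1a by -0.18 ± 0.14 and Nkx6-1 by -0.16 ± 0.12. The differences of Cdk5r1, Vgf and Fos were 0.16, -0.22 and 0.20, and none of these 7 genes passed with all arrays. Ube2c lost its call without Nr4a3 replicate 1 (limma adjusted p = 0.0510), and Mki67 without GFP replicate 1, 2, 3 or 5 or Nr4a3 replicate 1 or 3 (0.0507 to 0.10). The list's median was 0.34 (camera adjusted p = 0.00189, and adjusted p = 0.146 with an estimated correlation).

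No acinar cell gene passed singly in the arrays labelled Nr4a3, 1 rose when adjusted over the list alone, and the median of the 24 was 0.84 (camera adjusted p = 0.000178, and adjusted p = 0.696 with an estimated correlation). Spink1 differed by 2.48 ± 0.69 (limma adjusted p = 0.0765, and 0.0482 without GFP replicate 4) and Pnlip by 1.31 ± 0.44 (adjusted p = 0.166). Among 24 beta cell genes, Gipr fell and Chgb, which encodes the granule protein chromogranin B, rose by 0.47 ± 0.09. When adjusted over the list alone 1 rose and 5 fell. The beta cell median was -0.28 (camera adjusted p = 7.57e-06, and adjusted p = 0.328 with an estimated correlation), and -0.14 without Nr4a3 replicate 2. Of 16 endothelial cell genes, Kdr and Flt1 fell and none rose, 5 fell when adjusted over the list alone and 11 without Nr4a3 replicate 2. Their median was -0.35 (camera adjusted p = 2.29e-09, and adjusted p = 0.146 with an estimated correlation). The fibroblast and stellate cell genes had a median of -0.12 with no gene passing (camera adjusted p = 0.0470, and adjusted p = 0.776 with an estimated correlation). Their call ended without GFP replicate 1, 3 or 4 or Nr4a3 replicate 2, 3 or 4 (0.0830 to 0.306).

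Both responses were compared gene by gene. Of the genes called against GFP, 213 rose and 23 fell in both comparisons, and none changed in opposite directions. Lists of these sizes drawn independently would share 15.3 rises and 0.638 falls. Both comparisons use the same GFP arrays, which alone ties them together: across genes the log2 changes correlated at r = 0.712, against 0.499 in simulated unchanged groups. The simulated spread was independent between genes and equal across arrays, unlike the data. The value of 0.499 is therefore the level that shared controls set on average. It does not show how far r would vary by chance where genes move together. With separate sets of 2 and 3 GFP arrays, the median over 20 splits was r = 0.566 and 32 shared genes (range 5 to 56), with a covariance of 0.0438 against 0.0503 with shared controls. The shared total of 236 became 479 without Nr4a3 replicate 2, 140, 126, 140 or 117 without GFP replicate 1, 2, 3 or 5, and 120 or 130 without Nr4a3 replicate 1 or 3. Among the 1277 genes called in either comparison, 1135 had the larger absolute change in the Nr4a1 arrays, a count that favours the comparison with more calls. Among the 274 genes called with Nr4a3, 154 had the larger absolute change in the Nr4a1 arrays.

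**Figure D3:**
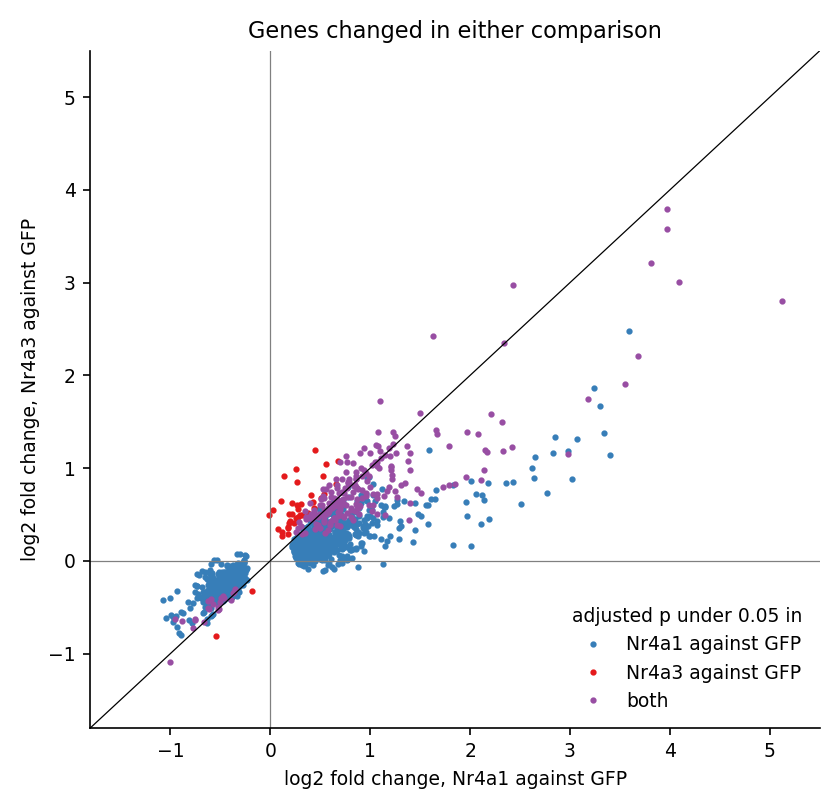
Each point is 1 of the 1277 genes called against GFP in the Nr4a1 or the Nr4a3 arrays, placed by its log2 fold change in the Nr4a1 arrays (horizontal) and in the Nr4a3 arrays (vertical), with a diagonal line of equal change. Of these, 236 were called in both, all in the same direction, and many of the large rises lie below the line, such as Fga at 5.12 and 2.80.

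The direct comparison of Nr4a1 with Nr4a3 tests where both responses differ. Gas2 was 3.13-fold higher in the Nr4a1 arrays (log2 1.65 ± 0.19, SE, n = 5 per group, limma adjusted p = 0.000194) and Gyg1, which encodes the primer of glycogen synthesis, 3.54-fold higher (1.83 ± 0.17, adjusted p = 2.14e-05). The cell cycle lists did not differ: the 49 G2/M and mitosis genes had a median of -0.01 (limma camera adjusted p = 0.907) and the 49 G1/S and E2F target genes a median of 0.00 (camera adjusted p = 0.907), and no gene of either list passed. In all, 85 genes were higher and 5 lower in the Nr4a1 arrays, 13 of them higher by at least 2-fold. A fit to only these 10 arrays called 1 gene, Gyg1, and a fit with array weights 274 (208 up, 66 down). Without Nr4a3 replicate 2 there were 116 and 17, and 85 of the 90 genes called before were among them. The total of 90 became 43 or 47 without Nr4a1 replicate 1 or 4, and 55 without Nr4a3 replicate 4. Group ranges did not overlap in 378 genes (2.66%), against 0.794% by chance.

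Other genes higher with Nr4a1 were the trypsinogen gene Prss3 (1.84 ± 0.41), the photoreceptor membrane protein gene Rom1 (1.24 ± 0.21), the transcription factor gene Dmrt2 (1.23 ± 0.18), the dopamine receptor gene Drd2 (1.19 ± 0.16), the purine oxidation gene Xdh (1.16 ± 0.21) and Prxl2b (1.12 ± 0.17). Those lower were Kctd12, a GABA receptor subunit gene (-0.50 ± 0.09), the fatty acid synthase gene Fasn (-0.41 ± 0.07), the Myc antagonist gene Mnt (-0.32 ± 0.07) and the RNA-binding protein gene Rbpms (-0.31 ± 0.07). Kctd12, Fasn, Mnt and Rbpms are 4 of the 5 genes that were lower. Acinar cell genes differed in the same direction, with 20 of 24 higher when adjusted over the list alone, only Prss3 over all genes, and a median of 1.60 (camera adjusted p = 4.89e-15, and adjusted p = 0.991 with an estimated correlation). The acinar mean was higher by 1.53 in the Nr4a1 arrays, all 5 above all Nr4a3 arrays (exact permutation p = 0.00794, two-sided, 0.222 after adjustment over the lists). Cela1 differed by 2.13 ± 0.50 (limma adjusted p = 0.0545, and 0.0423 to 0.0485 without Nr4a3 replicate 1 or Nr4a1 replicate 2 or 3). None of the 10 genes of the study differed, with log2 differences from -0.26 for Nkx6-1 to 0.23 for Ube2c and a list median of 0.00 (limma camera adjusted p = 0.805). For E2f1, Ccne1, Cdkn1a, Uhrf1 and Mki67 they were 0.07, -0.22, 0.00, 0.00 and 0.00, and for Cdk5r1, Vgf and Fos -0.18, 0.16 and -0.07. Nr4a1, Nr4a2 and Nr4a3 themselves differed by -0.10, -0.39 and 0.25 and did not pass. Prss3 lost its call without Nr4a1 replicate 1, 4 or 5 or Nr4a3 replicate 2, 3, 4 or 5 (limma adjusted p from 0.0605 to 0.172), Mnt without Nr4a1 replicate 1, 2 or 4 or Nr4a3 replicate 5 (0.0629 to 0.137) and Rbpms without Nr4a1 replicate 1, 2, 4 or 5 or Nr4a3 replicate 1, 3, 4 or 5 (0.0519 to 0.146).

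Energy metabolism and protein synthesis lists passed camera as higher with Nr4a1 than with Nr4a3, through small shifts in which no gene passed singly or when adjusted over the list alone. The 38 oxidative phosphorylation genes had a median log2 difference of 0.27 (camera adjusted p = 2.99e-08), the 20 glycolysis genes one of 0.17 (camera adjusted p = 0.00168) and the 18 ribosomal protein genes one of 0.22 (camera adjusted p = 0.00410, and adjusted p = 0.991 with an estimated correlation for each of them). Their means per array did not pass by exact permutation (p = 0.0952, 0.103 and 0.302 in that order, two-sided, adjusted 0.963, 0.963 and 0.992). In this comparison fry called 0 lists with all arrays, and without Nr4a3 replicate 2 it called 0 by direction and 4 in its mixed form. Without Nr4a3 replicate 2 the ribosomal protein list lost its call (median 0.01, camera adjusted p = 0.347) while the medians of oxidative phosphorylation and glycolysis genes were 0.06 and 0.11 (camera adjusted p = 0.00128 and 0.00663, and adjusted p = 0.885 with an estimated correlation for both). Single genes of other lists differed: the CDK inhibitor gene Cdkn2d was higher by 0.61 ± 0.11, Acadvl of fatty acid oxidation by 0.72 ± 0.13, Acat2 of cholesterol synthesis by 0.63 ± 0.13 and the chaperone gene Hsph1 by 0.49 ± 0.10 (log2 ± SE, n = 5 per group). Acat2 lost its call without Nr4a1 replicate 1, 2 or 4 or Nr4a3 replicate 4 (limma adjusted p from 0.0571 to 0.105), and Hsph1 without Nr4a1 replicate 1 or 4 or Nr4a3 replicate 4 (0.0586 to 0.0635). With Cdkn2d, 1 of 12 CDK inhibitor and RB family genes differed over all genes, and 1 was higher and 1 lower when adjusted over the list alone (list median -0.08, limma camera adjusted p = 0.886). The median of the cholesterol synthesis list was 0.17, and with single arrays left out it passed only without Nr4a3 replicate 5 (camera adjusted p = 0.0575, and 0.00880 without that array). Of such fits, the beta cell list passed only without Nr4a3 replicate 2 (median -0.16, camera adjusted p = 2.53e-05, and adjusted p = 0.660 with an estimated correlation) or Nr4a1 replicate 3 (0.0315), the anaphase-promoting complex only without Nr4a3 replicate 1 or Nr4a1 replicate 2 or 3 (0.0132 to 0.0439) and the beta cell disallowed genes only without Nr4a3 replicate 5 (0.0394). After a repeated quantile normalization camera called 5 lists, 4 higher and 1 lower, against 4 higher and 0 lower before.

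GFP against untreated islets gives the response to the control virus. No gene passed with limma (smallest adjusted p = 1.0), and unadjusted p lay under 0.05 for 412 genes, or 855 without Nr4a3 replicate 2, where chance alone would give 711. Group ranges did not overlap in 86 genes (0.605%), against 0.794% by chance. As lists, macrophage and leukocyte genes (median log2 -0.22, 22 genes) and endothelial cell genes (-0.18, 16 genes) were lower in the GFP arrays and NF-kB and inflammatory genes higher (0.23, 35 genes), each with a camera adjusted p of 0.00276, and adjusted p = 0.950 with an estimated correlation. The complement genes C1qa and C1qb differed by -0.80 ± 0.58 and -0.89 ± 0.55 (SE, n = 5 per group), the chemokine gene Ccl20 by 0.74 ± 0.46, C3 by 0.62 ± 0.78 and the endothelial gene Emcn by -0.32 ± 0.18. Exocytosis and calcium channel genes had a median of 0.08 (22 genes, limma camera adjusted p = 0.00140), with Cplx2 of synaptic vesicle fusion at 0.38 ± 0.20, and cholesterol synthesis genes one of 0.08 (21 genes, camera adjusted p = 0.0151). G2/M and mitosis genes had a median of -0.11 (49 genes, camera adjusted p = 0.0162) and p53 target genes one of 0.05 (18 genes, camera adjusted p = 0.0217), and none of these 4 calls held either (adjusted p = 0.950 with an estimated correlation). The 3 genes of the NR4A family and the 10 genes of the study did not pass, from -0.20 ± 0.24 for Ube2c to 0.31 ± 0.37 for Vgf. E2f1, Ccne1, Mki67 and Nkx6-1 differed by -0.15, -0.10, -0.14 and 0.04, and Cdkn1a, Uhrf1, Cdk5r1 and Fos by 0.13, 0.06, 0.01 and 0.19. Nr4a1, Nr4a2 and Nr4a3 differed by 0.02, 0.05 and -0.20.

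Single arrays decided 6 of these 7 list calls, with these camera adjusted p. The macrophage and leukocyte list lost its call without untreated replicate 1 or 5 or GFP replicate 5 (0.0844 to 0.104), the endothelial list without the same arrays (0.0514 to 0.134) and the NF-kB and inflammatory list without untreated replicate 1 or GFP replicate 2 or 5 (0.0900 to 0.422). The cholesterol synthesis list lost it without untreated replicate 3 or 4 or GFP replicate 4 (0.0596 to 0.125), the G2/M and mitosis list without untreated replicate 1 or 5 or GFP replicate 1, 3 or 5 (0.0623 to 0.718), and the p53 target list without untreated replicate 1, 2 or 5 or GFP replicate 1 or 5 (0.0514 to 0.103). The exocytosis and calcium channel list kept its call. Other lists did not pass with all arrays but passed with an array left out: acinar cell genes, lower in the GFP arrays by a median of -0.40, without untreated or GFP replicate 2 or 4 (4.97e-09 to 0.000916), and fibroblast and stellate cell genes without GFP replicate 1, 3 or 4 or untreated replicate 3 or 4 (0.000235 to 0.0236). The same held for unfolded protein response genes without untreated replicate 3 or 4, GFP replicate 4 or Nr4a3 replicate 2 (0.00262 to 0.0302), beta cell genes without untreated replicate 1 or GFP replicate 2 (0.0180 to 0.0208), G1/S genes without untreated replicate 3 (0.0295) and immediate early genes without GFP replicate 1 (0.0346).

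**Figure D4:**
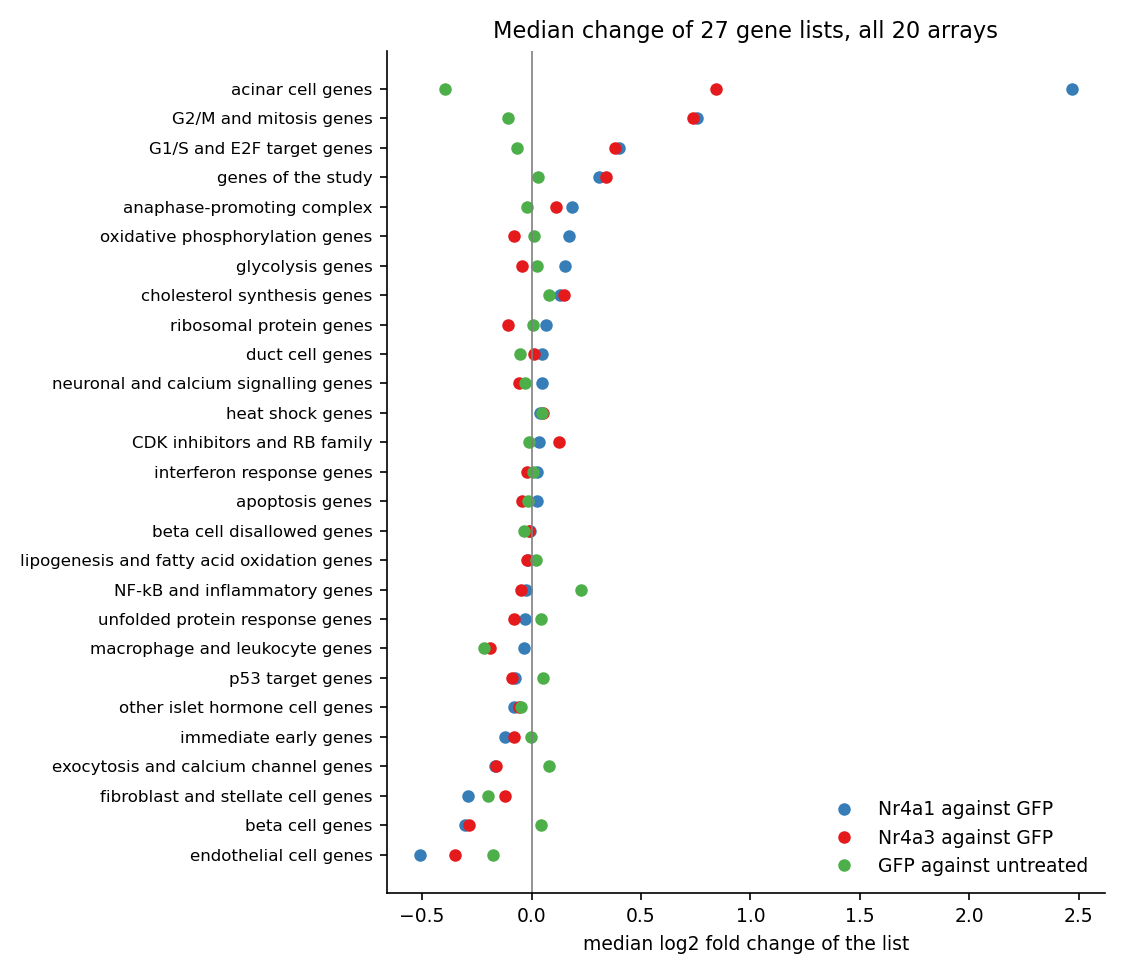
Each point is the median log2 fold change of 1 of the 27 gene lists, for Nr4a1 against GFP, Nr4a3 against GFP or GFP against untreated, over all 20 arrays. Acinar cell genes lie at 2.47, 0.84 and -0.40, G2/M and mitosis genes at 0.76, 0.74 and -0.11, and endothelial cell genes at -0.51, -0.35 and -0.18.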

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

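The fits of the G2/M mean with the acinar mean as a covariate were chosen before their result was seen; setting their bounds against 0, and all other tests given here as weighing an explanation, were chosen only after.

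Acinar cell genes set the arrays labelled Nr4a1 apart: their mean exceeded that of the GFP arrays by 2.39 on the log2 scale, in 5 of 5 arrays (exact permutation p = 0.00794, two-sided, the smallest possible). The added Nr4a1, which the design names, stays open as the biological explanation, and that p only restates the difference. More acinar cells of unchanged profile in those samples could do the same, since the mean also ran from 7.10 to 10.47 in the untreated arrays and the abundant acinar transcripts Prss1 and Ctrb1 averaged 13.90 and 13.58 in the Nr4a1 and 11.05 and 11.63 in the GFP arrays. Log-scale fits gave each acinar gene a slope on the mean of the other acinar genes, common to the Nr4a1, GFP and untreated arrays. In these, 6 of 24 genes differed in the Nr4a1 arrays (ordinary linear fits, adjusted over the list alone). Cpa1, Pnliprp2, Ctrb1 and Ptf1a lay lower and Cela1 and Pnlip higher, and such offsets partly balance by construction. The same fits gave 7 genes for the Nr4a3 arrays, whose acinar mean rose less, and at most 1 in 126 splits of the controls. Against GFP alone no gene differed, so carried-over acinar tissue and a change in acinar expression cannot be told apart, and both may hold.

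G2/M and mitosis genes rose in the arrays of both receptors, and dividing acinar cells may contribute. With the acinar mean as a covariate the rise of the G2/M mean in the Nr4a3 arrays was 0.60 (95% interval 0.31 to 0.89, and 0.25 to 0.87 without Nr4a3 replicate 2), against 0.73 without it, which argues against acinar content as the whole cause there but not as a part. In the Nr4a1 arrays it was 0.38 (-0.015 to 0.78), against 0.74, an interval too wide to tell acinar content and receptor apart. Only a G2/M rise in strict proportion to the acinar rise on the log scale is argued against. Both G2/M rises were alike while the acinar rises were 2.39 and 0.87, and the difference of the cross products was -1.10 (95% interval -1.94 to -0.26). More acinar cells need not raise both lists in that proportion, so this does not decide whether they contribute. The added receptors, named by the design, stay open as the biological explanation, and the covariate fit assumes a straight line on the log scale.

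Nr4a3 replicate 2 was far from the others of its group in its mean correlation with the other arrays, with a gap of 0.965 of the group's range. Degraded RNA is a candidate explanation: its beta-actin 3' minus 5' difference was 4.62 (1.5 to 2.21 in the other 19 arrays) and its GAPDH difference was 2.06 (0.27 to 0.74). Its BioB spike control, at 12.4 against 8.48 to 10.1, also lay outside the others and is added after extraction, so less labelled RNA may be part of it. The mean of Sct and Gucy2c was 8.71 in this array, 5.67 to 6.32 in the 10 controls and 9.09 to 10.54 in the other Nr4a1 and Nr4a3 arrays. Both genes were named with Nr4a3 under a rule that required all Nr4a3 arrays, this one included, to lie beyond all GFP arrays. They were also among the largest rises with Nr4a1, a choice this array entered only through the shared estimate of spread. Their mean in this array lay above the highest control by far more than the control SD of 0.22. For these genes that argues against a GFP or untreated sample under its label. Both rose with each receptor, so they do not tell an Nr4a1 from an Nr4a3 sample. No biological explanation was tested for a single array. Among the other 19 arrays, the 5 Nr4a1 arrays had the lowest GAPDH differences (0.271 to 0.357, and at least 0.408 in the rest), so this measure also went with that label. Whether RNA quality adds to the differences between the Nr4a1 arrays and the other groups was not tested.

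Whether other splits of the arrays call as many genes was counted over 100 splits of each set of 10 arrays, the real one included. For Nr4a1 against GFP chance is argued against, with 1239 genes in the real split and at most 3 in any other, so that 1 of 100 reached the real count. For Nr4a3 against GFP it is argued against too (274 genes, at most 4 in another, 1 of 100). For Nr4a1 against Nr4a3 with all arrays 1 of 100 reached the real count as well, but another split called 73 genes against 90. Of 126 possible splits 100 were counted, so chance is not excluded there. The count of 90 was 43, 47 or 55 without Nr4a1 replicate 1, Nr4a1 replicate 4 or Nr4a3 replicate 4. It was 1 in a fit to only these 10 arrays, for which other splits were not counted. For GFP against untreated the real count is 0, which 100 of 100 splits reach by construction (at most 1 gene in another), so the count of splits says nothing about chance there.

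Of the 90 genes called in the direct test, the following 16 named genes differed between the arrays labelled Nr4a1 and Nr4a3, all with limma at n = 5 per group. Whether the receptors caused these differences was not tested. Higher in the Nr4a1 arrays on the log2 scale were Prss3 (1.84), Gyg1 (1.83), Gas2 (1.65), Rom1 (1.24), Dmrt2 (1.23), Drd2 (1.19), Xdh (1.16), Prxl2b (1.12), Acadvl (0.72), Acat2 (0.63), Cdkn2d (0.61) and Hsph1 (0.49). Lower were Kctd12 (-0.50), Fasn (-0.41), Mnt (-0.32) and Rbpms (-0.31). Under at least 1 alternative 15 of these 16 lost their call, all but Gyg1, and in a fit to only the 10 arrays Gyg1 alone was called. Probe sets left out of the comparisons because they carry no single gene name also changed: 330 of 10216 for Nr4a1 against GFP (186 up, 144 down) and 56 for Nr4a3 against GFP (46 up, 10 down), against 0 for GFP against untreated.

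Single arrays lay far from the other 4 of their group in named genes. An array was marked when its gap to the nearest other was above 0.71 of the group's range, which chance gives in about 1 of 20 groups. In all, 31 of 428 groups were marked against 21.4 by chance, 6 of them through Nr4a3 replicate 2. GFP replicate 4 was highest in Ube2c (0.858), Spc25 (0.823), Ccnb1 (0.748) and Nnat (0.715) and lowest in Ccl20 (0.881) and Nefm (0.737). It was also highest in the means of G2/M and mitosis genes (0.742) and of CDK inhibitors and the RB family (0.739), and lowest in mean correlation (0.857). Nr4a3 replicate 2 was lowest in the means of exocytosis (0.891), unfolded protein response (0.8635), beta cell (0.767) and neuronal genes (0.764), and highest in Dmrt2 (0.728). Fga was highest in untreated replicate 2 (0.951) and lowest in Nr4a1 replicate 3 (0.805), where Igfbp3 was lowest as well (0.745). Fos was highest in GFP replicate 5 (0.754) and Nr4a3 replicate 3 (0.730), Pole (0.8575) and Hsph1 (0.741) in GFP replicate 2, Bdnf in untreated replicate 5 (0.781) and Prss3 in Nr4a3 replicate 1 (0.732). Gas2 was lowest in Nr4a1 replicate 5 (0.805), where the cholesterol synthesis mean was highest (0.736). Lowest in Nr4a1 replicate 4 were Rnf152 (0.713), Syt7 (0.724) and Cplx2 (0.721), and in untreated replicates 5 and 1 Il6r (0.734) and Prxl2b (0.724).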

How the results depend on the processing

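Among the alternatives, leaving Nr4a3 replicate 2 out of every comparison, alone or with the replicate block, was chosen only after seeing the data. Of the named genes called, 39 of 48 for Nr4a1 against GFP, 14 of 36 for Nr4a3 against GFP and 1 of 16 for Nr4a1 against Nr4a3 kept their call under all alternatives that gave them a value, and none reversed. Ccne1, Sct, Gucy2c and Nnat kept their calls against GFP with both receptors, Ccne1 at log2 changes of 0.73 to 0.89 with Nr4a1 and 0.94 to 1.15 with Nr4a3. Gyg1 was the 1 that kept its call in the last of these. Genes removed by a filter on dim probe sets gave no value there. Ranges of adjusted p given above with lost calls of named genes are for single arrays left out, and other alternatives went further for some. With limma it reached 0.613 for Cdc16 and 0.402 for Ryr2 with Nr4a3, 0.319 for Cdkn1b with Nr4a1, and 0.333 for Rbpms between the receptors.

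For Nr4a1 against GFP, 1239 genes became 2853 in a fit to only the 10 arrays compared, 3576 with array weights, 2714 without Nr4a3 replicate 2 and 2568 without it in the replicate block. They became 151 at a log2 change of at least 1 and 599 at an adjusted p under 0.01. For Nr4a3 against GFP, 274 became 122 with only the 10 arrays, 135 in the genes brighter than the median, 59 at a log2 change of at least 1, 86 at the stricter p and 1027 with array weights. For Nr4a1 against Nr4a3, 90 became 1 with only the 10 arrays, 13 at a log2 change of at least 1, 36 at the stricter p and 274 with array weights. The overlap of 236 became 118, 124, 47, 74 and 902 with only the 10 arrays, the genes brighter than the median, a log2 change of at least 1, the stricter p and array weights.

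Stricter thresholds and fewer genes lower a count by construction. Nr4a3 replicate 2 had an array weight of 0.0419, against 0.547 to 2.81 for the other 19, and it is absent from the fit to the Nr4a1 and GFP arrays. For the other shifts the cause was not tested. Other settings left these totals within 1.5 times, but by direction the 25 falls for Nr4a3 against GFP became 13 in the replicate block, 18 with only the 10 arrays, 37 after median centring, 38 with untreated as the control, 55 after a repeated quantile normalization and 240 with array weights, and GFP against untreated gave 0 genes under each. With the replicate block the counts were 1088, 204, 70 and 0, with 180 shared. Residuals of the 30 pairs of arrays with the same number had a median correlation of -0.03 across genes (-0.30 to 0.50), and genes are not independent replicates. The 120 pairs with different numbers ran from -0.60 to 0.58. These values give no sign that equal numbers pair the arrays, but they cannot exclude that some share an islet preparation.

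With each array of the groups compared left out in turn, the count was 742 (without Nr4a1 replicate 1) to 1238 for Nr4a1 against GFP, 127 (without Nr4a3 replicate 1) to 527 (without Nr4a3 replicate 2) for Nr4a3 against GFP, and 43 (without Nr4a1 replicate 1) to 133 (without Nr4a3 replicate 2) for Nr4a1 against Nr4a3. The overlap was 117 (without GFP replicate 5) to 479 (without Nr4a3 replicate 2). Beyond 1.5 times also lay, for Nr4a3 against GFP, GFP replicates 1, 2, 3 and 5 (158, 137, 160 and 130) and Nr4a3 replicate 3 (144), for Nr4a1 against Nr4a3, Nr4a1 replicate 4 (47) and Nr4a3 replicate 4 (55), and for the overlap GFP replicates 1, 2 and 3 (140, 126 and 140) and Nr4a3 replicates 1 and 3 (120 and 130). The cause was not tested.

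Lists called by camera numbered 12, 12, 4 and 7 in the comparisons of Nr4a1 with GFP, Nr4a3 with GFP, Nr4a1 with Nr4a3 and GFP with untreated. With an estimated correlation they numbered 0 in each, also without Nr4a3 replicate 2, while fits without another single array used the preset correlation alone. Directional fry called 9, 5, 0 and 0 and mixed fry 15, 6, 0 and 0, a different question from camera's. Without Nr4a3 replicate 2 directional fry called 11, 9, 0 and 0 and mixed fry 23, 12, 4 and 0. In the genes brighter than the median the lists called by camera numbered 9, 9, 4 and 4. With single arrays left out they were 10 to 14, 9 to 14, 4 to 6 and 2 (without GFP replicate 5) to 9 (without untreated replicate 3), and 3 without untreated replicate 1 or 5. The median of the genes of the study in the comparison of Nr4a1 with GFP turned to -0.12 in the genes brighter than the median, where fewer of them remained.

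Signal over background limits dim genes, whose changes RMA can compress. Nr4a1 and Nr4a3 lay near 6 on a log2 scale that starts at 2.94. The mean of Sct and Gucy2c began at a like level, 5.67 to 6.32 in the control arrays. It reached 9.09 to 10.54 in the Nr4a1 and Nr4a3 arrays other than Nr4a3 replicate 2. A level near 6 therefore need not hide a large change, and how far it compressed those of Nr4a1 and Nr4a3 was not tested. At the bright end Ins1 lies at the top of the scale.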

Other observations

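Fits without Nr4a3 replicate 2 were chosen only after the data were seen; the lists and other alternatives were fixed before.

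Cholesterol synthesis genes rose in part with Nr4a1: Stard4, which carries cholesterol between membranes, by 0.77 ± 0.10 and the squalene synthase gene Fdft1 by 0.87 ± 0.12 (log2 ± SE, n = 5 per group). Of 21 genes 5 rose and none fell, 5 when adjusted over the list alone, and the median was 0.13 (camera adjusted p = 0.00216, and adjusted p = 0.270 with an estimated correlation). With Nr4a3, Stard4 rose by 0.52 and Fdft1 by 0.59, the only 2 over all genes or when adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0644). That list passed without GFP replicate 2 or 4 or Nr4a3 replicate 2 or 4 (0.00843 to 0.0468, and adjusted p = 0.465 with an estimated correlation without Nr4a3 replicate 2).

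Genes of neurons and calcium signalling went both ways with Nr4a1: 4 of 21 rose and 2 fell, 5 and 2 when adjusted over the list alone. The neurofilament gene Nefm rose by 1.0 ± 0.18 and the monoamine transporter gene Slc18a2 by 0.90 ± 0.17 (median 0.05, limma camera adjusted p = 0.408). With Nr4a3 the growth cone gene Gap43 rose by 1.16 ± 0.22 and the neurotrophin gene Bdnf by 0.62 ± 0.13, 4 rose when adjusted over the list alone, and the median was -0.06 while the mean was 0.08 and camera's direction up (camera adjusted p = 0.465). Bdnf lost its call without Nr4a3 replicate 1 (limma adjusted p = 0.0557). Of 22 exocytosis and calcium channel genes 4 fell with Nr4a1, also when adjusted over the list alone, among them the calcium sensor gene Syt7 (-0.62) and the channel gene Cacna1c (-0.48), with a median of -0.17 (camera adjusted p = 0.0168, and adjusted p = 0.609 with an estimated correlation). With Nr4a3, Ryr2, which encodes a calcium release channel, changed by -0.51 and Cacna1c by -0.38, 3 fell when adjusted over the list alone, and the median was -0.16 (camera adjusted p = 0.000747, and adjusted p = 0.449 with an estimated correlation). That median was -0.03 without Nr4a3 replicate 2, and the mean difference went from -0.21 to -0.07 (camera adjusted p = 0.050, and adjusted p = 0.532 with an estimated correlation). Ryr2 lost its call without GFP replicate 1, 2, 4 or 5 or Nr4a3 replicate 1, 2, 3 or 5 (limma adjusted p from 0.050 to 0.114), and Cacna1c without GFP replicate 1, 2, 4 or 5 or Nr4a3 replicate 1 or 5 (0.0715 to 0.114).

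The secretory stress regulator gene Xbp1 rose by 0.74 ± 0.10 with Nr4a1 and by 0.47 ± 0.10 with Nr4a3, while the 27 unfolded protein response genes as a list did not pass (medians -0.03 and -0.08, camera adjusted p = 0.474 and 0.337). Usp18, an interferon-induced protease gene, rose by 0.86 ± 0.18 and 0.89 ± 0.18, and without GFP replicate 5 its call with Nr4a3 ended (limma adjusted p = 0.0501). Of 46 interferon response genes 3 rose with Nr4a1, 2 when adjusted over the list alone, and 1 with Nr4a3 (medians 0.03 and -0.02, camera adjusted p = 0.506 and 0.718).

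Oxidative phosphorylation genes were slightly higher with Nr4a1, where 2 of 38 rose, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.00193, and adjusted p = 0.754 with an estimated correlation). Without Nr4a3 replicate 2, 19 rose. With Nr4a3 the median was -0.08 (camera adjusted p = 0.167). It was -0.16 and -0.15 and passed without Nr4a3 replicate 1 or 3 (0.0358 and 0.0121), and turned to 0.11 without Nr4a3 replicate 2 (camera adjusted p = 4.42e-07, and adjusted p = 0.465 with an estimated correlation). Of 30 immediate early genes 3 fell with Nr4a1, also when adjusted over the list alone, and none with Nr4a3. The medians were -0.12 and -0.08 (camera adjusted p = 0.0471 and 0.0470, and adjusted p = 0.609 and 0.610 with an estimated correlation). That call ended with Nr4a1 without GFP replicate 2, 3 or 5, Nr4a1 replicate 2, 3 or 4 or Nr4a3 replicate 2 (0.0625 to 0.123), and with Nr4a3 without GFP replicate 2, 3 or 5 or Nr4a3 replicate 4 or 5 (0.0587 to 0.312). Of 18 p53 target genes 1 fell with Nr4a1, 2 when adjusted over the list alone, and none with Nr4a3 (medians -0.08 and -0.09, limma camera adjusted p = 0.0648 and 0.0410, and adjusted p = 0.398 with an estimated correlation for the second). It passed with Nr4a1 without GFP replicate 4 or Nr4a1 replicate 5 (0.0189 to 0.0399), and its call with Nr4a3 ended without GFP replicate 1, 2 or 5 or Nr4a3 replicate 2 or 5 (0.0598 to 0.122).

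The remaining lists did not pass in either comparison with GFP over all arrays. Medians with Nr4a1 and Nr4a3 were -0.03 and -0.05 for NF-kB and inflammatory genes (camera adjusted p = 0.454 and 0.353), -0.02 and -0.02 for lipogenesis and fatty acid oxidation genes (0.854 and 0.382), 0.15 and -0.04 for glycolysis genes (0.157 and 0.210) and 0.02 and -0.05 for apoptosis genes (0.864 and 0.921). They were 0.04 and 0.05 for heat shock genes (0.668 and 0.922) and 0.06 and -0.11 for ribosomal protein genes (0.339 and 0.101). With Nr4a3 they were -0.19 for macrophage and leukocyte genes (0.178), 0.01 for duct cell genes (0.937), -0.06 for other islet hormone cell genes (0.167) and -0.01 for beta cell disallowed genes (0.285). Median and camera's direction differed in sign for apoptosis genes with Nr4a1, for duct cell and heat shock genes with Nr4a3, for interferon response genes with Nr4a3 and for beta cell disallowed genes with Nr4a1. The medians with Nr4a3 turned without Nr4a3 replicate 2 to 0.06 for ribosomal protein genes (camera adjusted p = 0.0540), 0.05 for unfolded protein response genes, 0.07 for neuronal genes, 0.0050 for glycolysis genes and 0.01 for interferon response genes, none of them passing. Leaving out 1 array gave calls for NF-kB genes (with Nr4a1 without GFP replicate 4, camera adjusted p = 0.00815; with Nr4a3 without GFP replicate 4 or Nr4a3 replicate 2, 0.00197 to 0.0204, and adjusted p = 0.760 with an estimated correlation without the latter), macrophage genes (with Nr4a3 without Nr4a3 replicate 5, 0.0121) and ribosomal protein genes (with Nr4a1 without Nr4a3 replicate 2, 0.0315, and adjusted p = 0.765 with an estimated correlation; with Nr4a3 without GFP replicate 4 or Nr4a3 replicate 1, 3 or 5, 0.0182 to 0.0377).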
